A study of Rattus norvegicus with 194 samples.

How the data were processed

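Bulk RNA sequencing libraries were analysed from the ventral dentate gyrus, the basolateral amygdala, the shell of the nucleus accumbens and the cingulate gyrus of male and female rats (Rattus norvegicus). Per the labels' protocols, RNA was extracted with a Qiagen AllPrep kit and libraries followed standard Illumina preparation. The deposited values are raw read counts per gene, 1 file per library. Per the submitters' processing notes, STAR and the rat build rn6 were used. Their versions, the gene annotation and any trimming are not given in the sources used here. Each file lists counts without strand and counts for either strand, together with totals of unmapped, multimapping, ambiguous and gene-free reads, which were kept out of library sizes and tests. Between 97.78% and 98.27% of the strand-assigned gene counts fell on the second strand in every library, so the counts of that strand were analysed. Reads that mapped but lay in no gene on that strand were 30.87% to 49.09% of the total, multimapping reads 10.21% to 15.95% and ambiguous reads 0.2036% to 0.3283%. The 10 most abundant genes took 5.75% to 9.888% of the gene counts, except 2.918% in the incomplete accumbens library of female H10.

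The files name 32545 genes by Ensembl identifier and do not pair them with symbols. A RefSeq name table for the assembly GRCr8 was searched, and 0 of the identifiers matched. The 35 gene lists and the rule for naming genes, all fixed before the data were examined, work on symbols and could not be applied, so no gene is named by symbol. In their place, the text prints for the sexes the 2 identifiers per direction with the smallest summed rank of p over the 4 regions, for the other comparisons the 2 with the smallest p, and for the title letters each gene past the threshold. This substitute was chosen after the data were seen. Genes that share reads with near-identical copies could not be marked for the same reason.

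Region and sex came from the labels. Of 194 libraries, 191 were assigned and 3 were left out of all comparisons because the title and the region or sex label disagreed. The title without its region letter was read as the animal. A letter H or L in the titles is not explained by the labels and is reported as that letter. 7 amygdala libraries of females had a second run on another lane, with the same tag in the file name. Their counts differed by a chi-square per degree of freedom of 1.42 to 1.54 over genes with at least 20 counts, against 3.1 to 16.4 for 22 pairs of different amygdala libraries of females, and each was summed with its first run. 2 further libraries marked as repeats, 1 in the accumbens and 1 in the cingulate gyrus, carried another tag than the library of the same title and stayed libraries of their own. By title each of the 2 comes from the same animal as its partner, but by tag it does not, and both members count as libraries in the comparisons of the sexes. In the cingulate gyrus the marked library (female L8R) carries the tag that female L8 has in the other regions, and its partner carries the tag of female L6. In the accumbens the marked library (male L12R) carries the tag of male L2. Which animals these are stays open. All other libraries of a region are taken as separate animals from their titles, which no label states outright. Male L7 of the cingulate gyrus also carries another tag than male L7 of the other regions. It stayed in all fits as the animal of its title. The tags of the 2 assigned libraries whose titles give no letter match those of animals in other regions, but the titles were followed.

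Libraries held 5041357 to 14022125 gene counts, with a median of 9084406. 2 accumbens libraries (female H10 and male L12R) had at least 100 genes at 0 that have over 50 counts in at least 90% of the libraries of the region; this definition was chosen after the data were seen. They stayed in the comparisons as planned, and values without them are given beside.

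Genes differing between the sexes were tested in each region alone with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust dispersions, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05, two-sided, with sex as the only term. The standard error of a log2 fold change is the fold change over the square root of F. Title letters H and L were compared in the same way with sex as a covariate. Dependence of the sex difference on region, and enrichment of genes in 1 region against the mean of the others (log2 fold change of at least 1), came from a single fit of 178 libraries of 47 animals with the animal as a block, without the 2 repeat-marked libraries of another tag (female L8R of the cingulate gyrus and male L12R of the accumbens), their partners and 2 libraries whose titles give no animal. Libraries of the same animal in 2 regions deviated together from their group means: the mean correlation over genes was 0.145 to 0.18 for the 6 pairs of regions, against -0.007 or -0.008 for different animals of the same sex. Sex differences were correlated across genes between regions on log2 CPM (prior count 2), without the genes that separated the sexes in all regions (which stand in for the planned Y and X lists), and compared with 100 permutations of sex over animals made in both regions at once. These permutations ignore the number in the file name, which groups animals of both sexes except for 2 numbers with males only. Of these 2, 1 is held only by male L7 of the cingulate gyrus, whose animal by title has another number elsewhere.

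The tests were run on simulated counts drawn with the means, dispersions and library sizes of the real data, with 200 genes changed before filtering. At a 1.25-fold change, 71.6% of such genes were called for the sexes in the dentate gyrus (13605 genes), 68.7% in the amygdala (14015), 74.6% in the accumbens (14089) and 88.1% in the cingulate gyrus (13465). For the title letters these shares were 84.8% in the dentate gyrus (13756 genes), 74.6% in the amygdala (14226), 69.7% in the accumbens (14309) and 79.1% in the cingulate gyrus (13627). At 1.5-fold, 97%, 92.4%, 95.5% and 98.5% were called for the sexes in the dentate gyrus, amygdala, accumbens and cingulate gyrus, and 98.5%, 98.5%, 79.1% and 100% for the title letters. At 2-fold these shares were 100%, 100%, 98.5% and 100% for the sexes and 100% in each region for the letters. Among unchanged genes, 5, 4, 8 and 6 were called for the sexes and 7, 10, 8 and 6 for the letters. Of 200 genes with a 1.5-fold sex difference in the amygdala alone, 85.5% were called for dependence on region (1999 genes). Of the 1799 genes without a simulated sex difference, 5 were called. Of 200 other genes raised 4-fold in the amygdala, 100% were called as enriched there, with 0 of the 1799 genes not raised. Each set of 1799 holds the changed genes of the other kind. Simulated libraries were drawn independently of one another, without effects of lane, file number or animal. The counts of unchanged genes called therefore leave out such structure in the real data.

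Alternatives fixed in the same way were RLE size factors, DESeq2 1.42.0, limma 3.58.1 voom, other filters on low counts, unstranded counts, the title letter, the lane or the number in the file name as covariates, a replicate block, 3 surrogate variables from sva 3.50.0, lanes with both sexes only and other treatments of repeats. limma's consensus correlation was estimated from 2000 genes. Other splits of the samples were refitted for the tests across regions with limma's trend method in place of edgeR, because of run time. Alternatives chosen after seeing the data were the share of reads outside genes as a covariate, the incomplete libraries left out, subsets of accumbens males by lane, and the accumbens left out of the test across regions. The lane and the sequencing run are those in the file name, and the same lane number in another run is a lane of its own. Accumbens lanes are given by number within the run that holds most accumbens libraries. The 2 accumbens males from lane 3 of the other run are named apart.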

Results

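Gene expression was measured by RNA sequencing in 4 cortico-limbic regions of male and female rats: the ventral dentate gyrus, part of the hippocampal formation; the basolateral amygdala; the shell of the nucleus accumbens, part of the ventral striatum; and the cingulate gyrus of the medial cortex. The series asks how expression differs between the sexes in these structures. After repeat runs were summed, the comparison of the sexes held 23 females and 24 males in the dentate gyrus, 23 and 23 in the amygdala, 23 and 23 in the accumbens shell and 21 and 24 in the cingulate gyrus. Gene counts per deposited library ranged from 5274826 to 11178479 in the dentate gyrus, from 6711460 to 13005883 in the amygdala, from 6703712 to 13938746 in the accumbens and from 5041357 to 14022125 in the cingulate gyrus.

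Against the mean of the other regions, 643 of 14841 genes were enriched in the dentate gyrus, 328 in the amygdala, 555 in the accumbens shell and 532 in the cingulate gyrus, at a log2 fold change of at least 1. The 2 genes with the smallest p in each region follow, with CPM as mean ± SD over 47 libraries of the dentate gyrus, 45 of the amygdala, 43 of the accumbens and 43 of the cingulate gyrus. For the dentate gyrus, ENSRNOG00000003694 was at 236.8 ± 40.5 CPM there, 11.91 ± 1.96 in the amygdala, 10.3 ± 2.15 in the accumbens and 10.54 ± 2.52 in the cingulate gyrus, a log2 fold change of 4.44 over the others (SE 0.038, edgeR adjusted p = 8.97e-128). ENSRNOG00000039300 had a log2 fold change of 1.72 (SE 0.017), with 351.3 ± 38.9 CPM in the dentate gyrus and means of 88.76, 131.9 and 102.7 in the amygdala, accumbens and cingulate gyrus. For the amygdala, ENSRNOG00000011589 was at 250.3 ± 23.2 CPM there, 29.23 ± 4.66 in the dentate gyrus, 151.3 ± 25.1 in the accumbens and 96.14 ± 9.88 in the cingulate gyrus, a log2 fold change of 1.75 (SE 0.026, edgeR adjusted p = 4.79e-99). ENSRNOG00000023337 had a log2 fold change of 2.75 (SE 0.043), with 51.21 ± 8.45 CPM in the amygdala and means of 1.36, 15.29 and 21.31 in the dentate gyrus, accumbens and cingulate gyrus. For the accumbens, ENSRNOG00000017712 was at 121.5 ± 20.7 CPM there, 2.82 ± 1.17 in the dentate gyrus, 4.55 ± 2.59 in the amygdala and 0.41 ± 0.39 in the cingulate gyrus, a log2 fold change of 6.19 (SE 0.063, edgeR adjusted p = 1.09e-117). ENSRNOG00000024061 had a log2 fold change of 3.71 (SE 0.047), with 138.7 ± 21.4 CPM in the accumbens and means of 7.11, 21.53 and 8.23 in the dentate gyrus, amygdala and cingulate gyrus. For the cingulate gyrus, ENSRNOG00000005342 was at 85.72 ± 6.68 CPM there, 10.76 ± 1.6 in the dentate gyrus, 28.97 ± 3.97 in the amygdala and 25.64 ± 3.3 in the accumbens, a log2 fold change of 2.10 (SE 0.025, edgeR adjusted p = 6.1e-111). ENSRNOG00000014367 had a log2 fold change of 2.57 (SE 0.032), with 439.1 ± 37.6 CPM in the cingulate gyrus and means of 86.98, 58.46 and 79.51 in the dentate gyrus, amygdala and accumbens. All 189 complete assigned libraries correlated best with the mean profile of the region on their label, a mean that includes the library itself. Region also went with the sequencing run in the file name. All dentate gyrus libraries came from 1 run, shared by 2 males each of the amygdala and accumbens and by part of the cingulate libraries. The rest came from another run. The fit has no run term, so enrichment was not parted from run.

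In every region a few genes separated females from males without overlap, and many more differed by small amounts. ENSRNOG00000057231 was at 126.1 ± 7.8 CPM (SD, n = 24) in males of the dentate gyrus and at 0.016 ± 0.042 CPM (SD, n = 23) in females. ENSRNOG00000060496 was at 82.84 ± 5.92 CPM (SD, n = 24) in these males and at 0.015 ± 0.040 CPM (SD, n = 23) in the females. In the opposite direction, ENSRNOG00000051257 was at 37.83 ± 10.8 CPM (SD, n = 23) in females and at 0.050 ± 0.082 CPM (SD, n = 24) in males. ENSRNOG00000055225 was at 10.9 ± 2.64 CPM (SD, n = 23) in females and had 0 counts in all 24 males, so that it was at least 747-fold higher in females, with the floor set at 3 counts over the male group, which covers counting error only. The same 4 genes passed the threshold in the same direction in the other regions. Across the 4 regions, 5 genes lay higher in every complete male library than in any complete female library, and 3 lay higher in every complete female library. Within the dentate gyrus alone, 5 genes separated the sexes in each direction, where chance gives such a separation to 1.24e-11% of genes. In all 189 complete assigned libraries the CPM of ENSRNOG00000055225 was above that of ENSRNOG00000060496 in females and below it in males; both genes were chosen from these libraries.

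In the dentate gyrus 983 of 13607 genes differed between the sexes, 483 higher in females and 500 higher in males. The median size of the called log2 fold changes was 0.14, and 7 genes differed over 2-fold. In the amygdala 1256 of 14018 genes differed, 722 higher in females and 534 higher in males, with a median of 0.17 and 15 genes over 2-fold. In the cingulate gyrus 378 of 13465 genes differed, 299 higher in females and 79 higher in males, with a median of 0.20 and 15 genes over 2-fold. That count was 169 with the share of reads outside genes as a covariate and 671 by limma voom with quality weights. With 3 surrogate variables the counts were 516 in the dentate gyrus and 2022 in the amygdala. Sex was unevenly spread over sequencing lanes. In the dentate gyrus only 1 of 6 lanes held both sexes, with 13 females and 2 males, and with lane as a covariate 9 genes were called, all 9 among those called without it. In the amygdala 2 of 5 lanes held both sexes (11 females, 15 males), and 45 genes were called with lane as a covariate. In the cingulate gyrus 4 of 7 lanes did (17 females, 21 males), and 94 were called. In the amygdala the 7 libraries of females summed with a second run count under the lane of their first run only. The plot of calls with and without lane sets the counts with lane beside those from shuffled lanes.

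**Figure D1:**
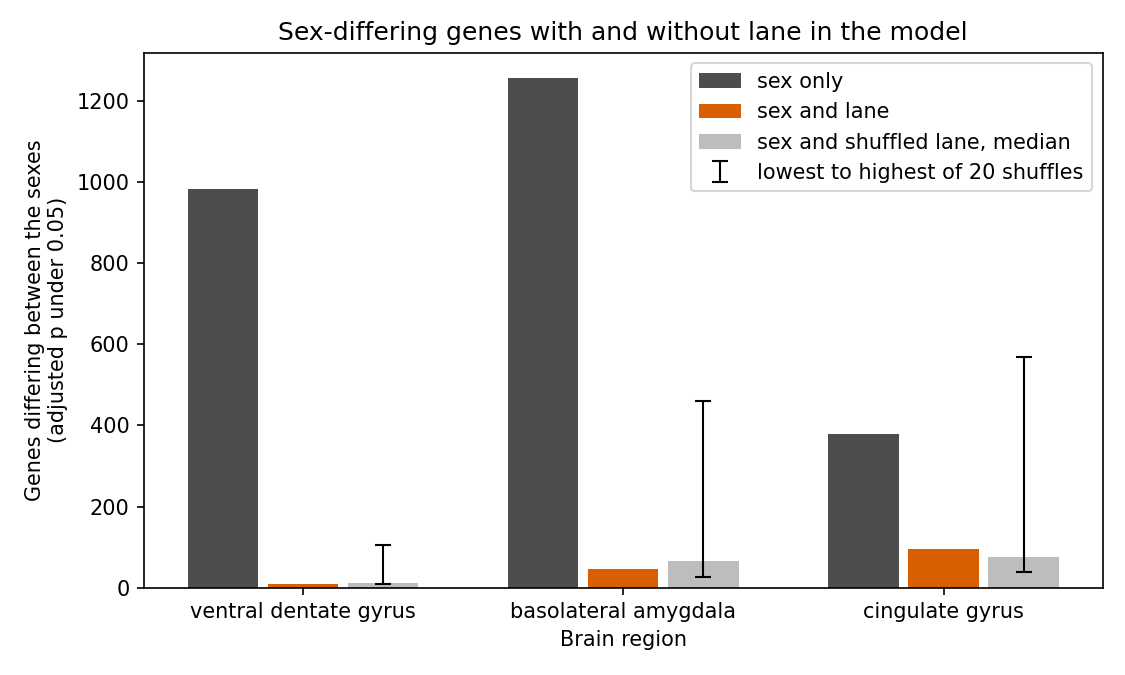
Genes differing between the sexes at an adjusted p under 0.05 (vertical axis, number of genes) in 3 regions, with sex alone in the model, with the sequencing lane added, and with lanes shuffled within each sex (bar at the median, line from the lowest to the highest of 20 shuffles). The counts with the real lanes, 9, 45 and 94, lie within the shuffled ranges of 9 to 104, 26 to 461 and 38 to 569.

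In the accumbens shell 6108 of 14090 genes differed between the sexes, 3020 higher in females and 3088 higher in males. The median size was 0.19 on the log2 scale, and 45 genes differed over 2-fold, 34 of them higher in females. Without the 2 incomplete libraries 6789 genes differed, 3316 higher in females and 3473 higher in males. No lane held accumbens libraries of both sexes, so lane and sex cannot be told apart there. Lane numbers here are those of the run that holds all accumbens females and most males, and 2 males came from lane 3 of another run. The males fell into lanes that differed from one another: 11 males of lanes 3 and 4 differed from 9 males of lanes 6 and 7 in 5487 of 13971 genes, while 9 females of lane 1 and 13 females of lane 2 differed in 0 of 14231 genes by edgeR (1031 at an unadjusted p under 0.05; no other tool was run). The males of lanes 3 and 4 mostly carried the letter L and those of lanes 6 and 7 mostly H. The test between these males has no term for letter or file number. The share of uniquely mapped reads outside genes was 47.66% ± 1.47 (SD, n = 11) in males of lanes 3 and 4. It was 53.83% ± 2.26 (SD, n = 9) in males of lanes 6 and 7 and 51.9% ± 2 (SD, n = 2) in males of the other run. In females it was 46.58% ± 1.72 (SD, n = 22). With this share as a covariate 2805 genes differed between the sexes. Without the incomplete libraries, females differed from the males of lanes 3 and 4 in 2339 genes. From the other 11 males, 9 of lanes 6 and 7 and 2 of the other run, they differed in 8446.

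**Figure D2:**
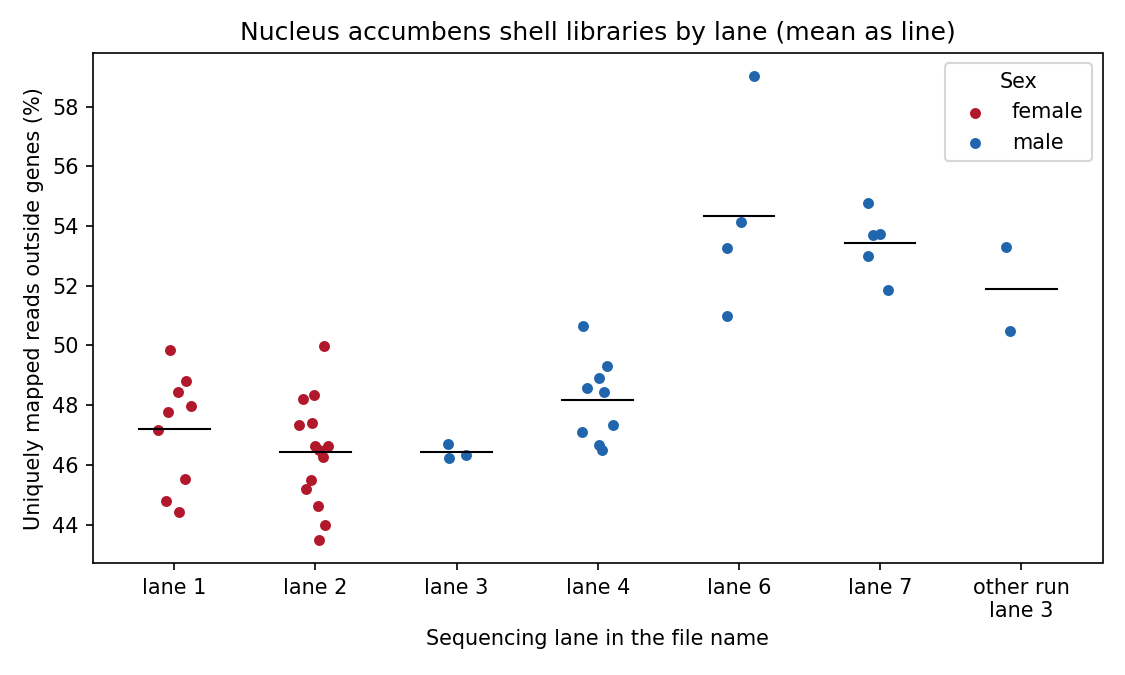
Share of uniquely mapped reads outside genes (vertical axis, percent) in each accumbens shell library by sequencing lane, females in red and males in blue, with the mean of each lane as a line. No lane holds both sexes, and the males of lanes 6 and 7 lie at 50.97% to 59.02%, above every female library. Males of another sequencing run are shown apart.

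A group of genes was higher in females in all 4 regions. Of 13104 genes tested in each region, 38 passed the threshold with higher expression in females in every region, against 0.127 for independent lists, and 7 did so with higher expression in males, against 0.0255. Regions share animals, so independent lists understate what chance gives. Without the separating genes, 36 genes were higher in females, with a median log2 fold change over genes and regions of 0.31 and a highest of 1.61, and 2 were higher in males. The fold change was smallest in the dentate gyrus for 27 of the 36. All dentate gyrus libraries came from the same sequencing run, and this difference between regions was not parted from run. With lane as a covariate all 36 kept a positive fold change in the amygdala (13 past the threshold) and in the cingulate gyrus (16 past the threshold), and 34 did so in the dentate gyrus (0 past the edgeR threshold, 11 at an unadjusted p under 0.05; no other tool was run with lane). Their median log2 fold change was 0.23 with lane and 0.25 without in the dentate gyrus, 0.31 and 0.31 in the amygdala, and 0.31 and 0.31 in the cingulate gyrus. In the accumbens against males of lanes 3 and 4 all 36 were positive and 31 passed. The 36 genes were chosen from these same libraries in every region. Their signs and medians in these refits therefore give no independent support.

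The size of the sex difference depended on region for 5618 of 14841 genes in the fit with the animal as a block (F test of the region by sex terms, edgeR), and for 6112 of 14834 genes without the incomplete female accumbens library. With the accumbens left out, 897 of 14516 genes showed such a dependence, 814 of them among the 5618. Neither test has a lane or run term, and all dentate gyrus libraries came from 1 run. Sex goes with lane wholly in the accumbens and in part elsewhere, where 5 of 6 lanes of the dentate gyrus, 3 of 5 of the amygdala and 3 of 7 of the cingulate gyrus held 1 sex. Other splits of the animals were not run for the 897, so chance is not excluded for that count. Over all 4 regions, splits other than the real one gave up to 1355 genes by limma's trend method. ENSRNOG00000043465 (adjusted p = 2.36e-16) was higher in females throughout. In the cingulate gyrus it was at 323.3 ± 92.1 CPM (SD, n = 21) in females and 106.1 ± 61.2 CPM (SD, n = 24) in males, a log2 fold change of 1.61 (SE 0.184, edgeR adjusted p = 3.2e-08). In the amygdala the log2 fold change was 1.19 (SE 0.104), in the accumbens 1.11 (SE 0.123) and in the dentate gyrus 0.43 (SE 0.075). With lane as a covariate the values for ENSRNOG00000043465 were 1.59 in the cingulate gyrus, 1.21 in the amygdala and 0.42 in the dentate gyrus, and the last did not pass the threshold (SE 0.214, edgeR adjusted p = 0.742). ENSRNOG00000002215 (adjusted p = 2.36e-16) was at 24.71 ± 6.33 CPM (SD, n = 23) in females and 13.26 ± 3.83 CPM (SD, n = 23) in males of the accumbens, a log2 fold change of 0.90 (SE 0.108). Its log2 fold changes of 0.11 in the dentate gyrus, -0.11 in the amygdala and -0.07 in the cingulate gyrus did not pass. Against accumbens males of lanes 3 and 4 alone the log2 fold change of ENSRNOG00000002215 was 0.86 (SE 0.144). With lane as a covariate it was 0.32 in the dentate gyrus (SE 0.168), -0.16 in the amygdala (SE 0.107) and -0.01 in the cingulate gyrus (SE 0.072), and none of the 3 passed by edgeR (adjusted p = 0.756, 0.695 and 0.981).

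**Figure D3:**
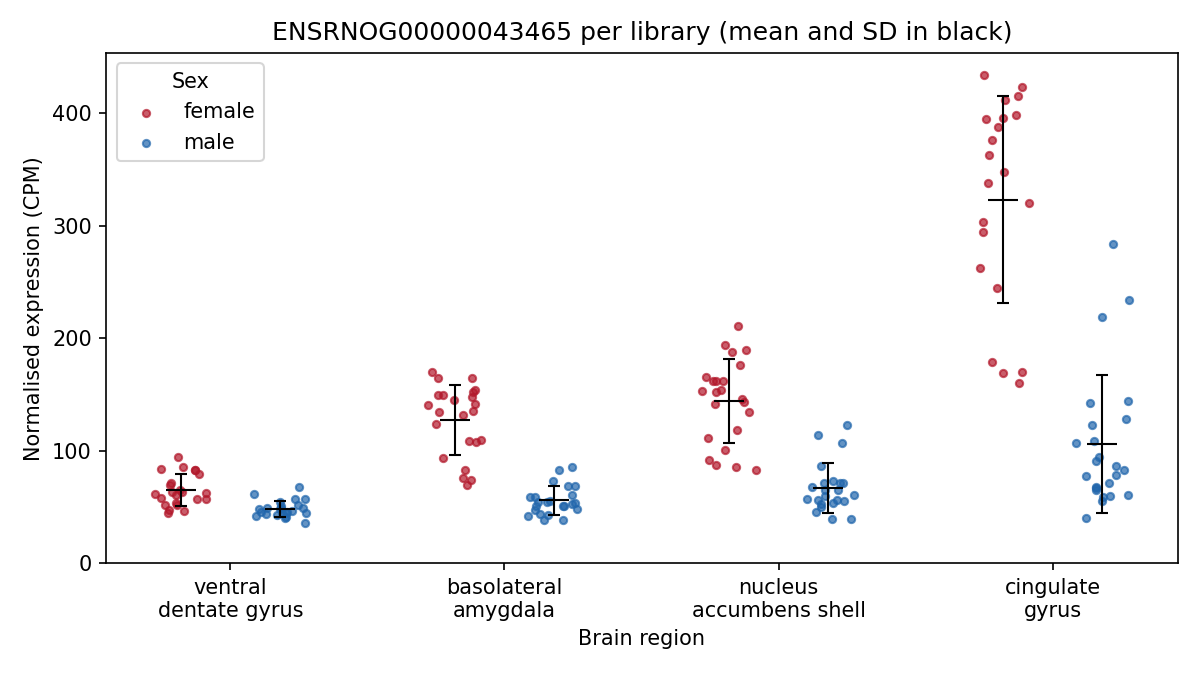
Normalised expression of ENSRNOG00000043465 (vertical axis, CPM) in each library of the 4 regions, females in red and males in blue, with mean and SD in black. The mean is higher in females in each region, from 64.99 against 48.41 CPM in the dentate gyrus to 323.3 against 106.1 CPM in the cingulate gyrus.

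Sex differences of the dentate gyrus were correlated across genes with those of the amygdala (Pearson r = 0.303, 45 animals, permutation p = 0.0099, adjusted over 6 pairs 0.03) and of the accumbens (r = 0.319, 43 animals, permutation p = 0.0099, adjusted 0.03). A p of 0.0099 is the smallest that 100 permutations can give, and the tests are one-sided. Genes are not independent replicates, and the median r under permuted sex was 0.162 and 0.094. For the amygdala and the accumbens r was 0.292 (41 animals, permutation p = 0.02, adjusted 0.04). Permuting sex over animals also breaks the link of sex with lane, which is whole in the accumbens and partial elsewhere. The permutation tests therefore do not part a shared sex difference from lane. For pairs with the accumbens lane could not be fitted. The amygdala and the cingulate gyrus (r = 0.301, permutation p = 0.059), the dentate and cingulate gyri (r = 0.221, permutation p = 0.35) and the accumbens and the cingulate gyrus (r = -0.035, permutation p = 0.98) did not pass. At a mean CPM of at least 10 no pair passed after adjustment (adjusted permutation p = 0.1 for dentate gyrus and amygdala, 0.059 for dentate gyrus and accumbens and 0.06 for amygdala and accumbens). Without the incomplete female accumbens library the values with the accumbens were 0.357 for the dentate gyrus and 0.325 for the amygdala, and over that family of tests no pair passed after adjustment (lowest adjusted permutation p = 0.059). Over all libraries, r of the edgeR fold changes went from 0.29 to 0.045 with lane in both fits for the dentate gyrus and the amygdala. It went from 0.262 to -0.001 for the dentate and cingulate gyri and from 0.313 to 0.222 for the amygdala and the cingulate gyrus. Lane raised the standard errors of the genes no longer called, by a median ratio of 2.63, 1.83 and 1.32 in the dentate gyrus, amygdala and cingulate gyrus. Such a loss of precision alone can lower r, and r with shuffled lanes was not computed.

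Titles with the letter H and titles with L differed in 1 gene at most per region after adjustment by edgeR. Each number in the file names carries 1 letter only. There were 10 numbers in the dentate gyrus, amygdala and accumbens and 11 in the cingulate gyrus, 5 with H in each region. The edgeR and DESeq2 fits have no term for this number and take libraries as independent. Their adjusted p can therefore be too small. No letter fit has a lane term in any region. Among accumbens males the letter went largely with lane, and the sets of male lanes compared above differed in 5487 genes. Neither the genes called for the letters in the accumbens nor the small number of them was parted from lane. In the dentate gyrus (24 H, 23 L) 1 of 13607 genes passed: ENSRNOG00000000407, at 5.79 ± 1.56 CPM (SD, n = 24) for H and 4.13 ± 0.84 CPM (SD, n = 23) for L, a log2 fold change of 0.49 (SE 0.093, edgeR adjusted p = 0.0363). In the accumbens (23 H, 22 L) 1 of 14112 passed: ENSRNOG00000019288 fell by 0.14 on the log2 scale (SE 0.025, edgeR adjusted p = 0.0463), from 55.63 ± 3.41 CPM (SD, n = 22) for L to 50.59 ± 2.79 CPM (SD, n = 23) for H. In the amygdala and the cingulate gyrus 0 genes passed by edgeR. Genes at an unadjusted edgeR p under 0.05 were 1362, 935, 1601 and 1060 in the dentate gyrus, amygdala, accumbens and cingulate gyrus. For independent libraries chance gives 680, 702, 706 and 671, which does not allow for the file numbers. The excess is therefore not shown to go beyond chance. DESeq2 called 29, 10, 13 and 21. limma with the number in the file name as a random block called 0 genes in each region (limma adjusted p = 0.25 for ENSRNOG00000000407 and 0.174 for ENSRNOG00000019288).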

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

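The tests of sex with the share of reads outside genes as a covariate and without the 2 incomplete libraries, the bound used for shallow sequencing, the spread over left-out libraries for that share the splits of whole file numbers and the tests on the slopes, with their gene set and their SD over shuffles, were chosen after the data were seen. Dependence of the sex difference on region was seen for 5618 genes, with the smallest adjusted p of 2.36e-16 for ENSRNOG00000043465 and of 2.36e-16 for ENSRNOG00000002215. Among 100 splits of the animals between the sexes, 1 (the real one) gave as many genes. The splits were fitted with limma's trend method because of run time. The real split gave 5482 genes and the highest other 1355, so chance can be excluded for the count over all 4 regions. These splits do not part sex from lane, and sex goes with lane wholly in the accumbens. The library titled CFH5, whose title and sex label disagree, held ENSRNOG00000055225 at 8.24 CPM and ENSRNOG00000051257 at 29.84 CPM, above the highest complete male library (0.4755 and 3.685 CPM) and within the range of females.

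More genes differed between the sexes in the accumbens shell than elsewhere; the difference between regions was tested per gene by the region by sex terms above, not as a difference between the counts. The 2 incomplete libraries as the whole cause are argued against by the 6789 genes that differed without them. A batch marked by lane is a candidate explanation: males of lanes 3 and 4 differed from males of lanes 6 and 7 in 5487 genes, and no lane holds both sexes. Title letter and file number also differ between these males, and that test has no term for them. The lane alone stays open. The same 7 amygdala libraries differed in 17 of 13867 genes between lanes 6 and 7, but neither lane holds accumbens females and both lie on the same side of the comparison of males above, so this test does not reach the lanes that go with sex. The share of reads outside genes stays open too: 2805 genes passed the threshold with it as a covariate (2517 of them also without it), 2405 to 3027 when each library was left out, against 1256 in the amygdala without the covariate and 1817 with it; the bounds were fewer genes than the amygdala and over 2 times as many, and against either count the range does not settle it. A biological difference between the sexes in this region remains among the open explanations.

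Adding lane lowered the count of sex-differing genes in the other regions, to 9 in the dentate gyrus, 45 in the amygdala and 94 in the cingulate gyrus. These counts lie within those from 20 shuffles of the lanes within each sex (9 to 104, 26 to 461 and 38 to 569). Less information on sex once lane is in the model can give such counts. In the dentate gyrus the real count equals the lowest of the shuffles, whose median was 11. There 5 genes separated the sexes in each direction, so the count could hardly fall lower and the shuffles do not decide. Differences between lanes as the whole cause are argued against by the slope of lane-adjusted on unadjusted fold changes over the lost genes, which was 0.932, 0.857 and 0.908, where this cause needs 0.3 or less and 0.7 or more speaks against it. The SD over shuffles was 0.227, 0.155 and 0.066, so that the dentate gyrus and the amygdala clear 0.7 by little more than that SD. The dentate gyrus slope rests on 1 lane with 13 females and 2 males. Differences between lanes as part of the cause stay open in each region. No biological explanation was tested.

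2 accumbens libraries, female H10 and male L12R, had 1000 and 301 genes at 0 among 10230 genes with over 50 counts in every other accumbens library. Of these, 92.8% and 91.4% stood in runs of 10 or more adjacent genes in file order, consistent with counting of an input that ended part way, and their unmapped reads were 0.122% and 0.115% of the total against 4.225% to 11.59% elsewhere. Shallow sequencing is argued against by 169 and 47 genes at 0 that had over 1000 counts in every other library, at totals within the range of the others. The bound set beforehand was 50 or more such genes in both libraries, which the 47 of male L12R do not reach, so that test alone would have left shallow sequencing open for it; the bound was lowered to 10 after the 47 was seen, because a total within the range leaves no room for such genes at 0. Another tissue or degraded RNA is argued against by the genes not at 0, whose median absolute log2 difference from the group median was 0.074 and 0.093, within the range of their groups (highest 0.09 and 0.131). No biological explanation was tested.

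Splits of the same libraries into groups of the same sizes gave, among 40 per region, 1 split (the real one) with as many sex-differing genes in each region. The real counts were 983, 1256, 6108 and 378 for the dentate gyrus, amygdala, accumbens and cingulate gyrus, and the highest others 1, 1, 0 and 4, so chance can be excluded. These splits do not part sex from lane. For the title letters, 1 of 40 splits of single libraries, the real one, gave as many genes in the dentate gyrus and in the accumbens (1 gene each, highest other 0). These splits ignore that each file number carries 1 letter. When whole file numbers were exchanged, 35 of 40 splits in the dentate gyrus and 23 of 40 in the accumbens gave at least 1 gene (highest others 91 and 105), so chance could not be excluded for the letters. Splits with that many genes point to a structure of the samples that goes with the file number. In the amygdala and cingulate gyrus the real count is 0, which all 40 of 40 splits reach by construction (highest others 0 and 1), so the splits say nothing there. For enrichment by region, 1 of 100 splits within animals, the real one, gave as many genes in each region with limma's trend method. The real counts were 609, 256, 483 and 491 genes and the highest others 0, 0, 32 and 33, so chance can be excluded. These splits do not part region from run.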

How the results depend on the processing

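The share of reads outside genes as a covariate, the subsets of accumbens males, the incomplete libraries left out and the accumbens left out were chosen after seeing the data. Counts not named here stayed within 1.5 times. For the sexes, lane as a covariate gave 9 genes in the dentate gyrus, 45 in the amygdala and 94 in the cingulate gyrus, and lanes with both sexes alone gave 10, 34 and 85 with fewer libraries; in the accumbens neither could be fitted. Surrogate variables gave 516 in the dentate gyrus and 2022 in the amygdala, voom with quality weights 671 in the cingulate gyrus, and the share of reads outside genes 2805 in the accumbens and 169 in the cingulate gyrus; the cause was not tested. Females against accumbens males of lanes 3 and 4 gave 2339, with fewer males and without the incomplete libraries. The 4 named sex genes kept direction and threshold in all 58 refits of the sex comparisons. Dependence on region fell to 897 genes without the accumbens. A log2 threshold of 2 left 197, 79, 189 and 107 region-enriched genes in the dentate gyrus, amygdala, accumbens and cingulate gyrus.

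Numbers in the titles do not pair females with males: the same letter and number correlated at 0.033, -0.013, 0.016 and -0.017 on average in the 4 regions. With that replicate block the sexes differed in 868, 883, 5547 and 364 genes. For the letters, sex and number as a replicate block gave 1, 0, 0 and 1 genes, and the gene of the dentate gyrus was not the one named.

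For title letters H and L, DESeq2 gave 29, 10, 13 and 21 genes in the dentate gyrus, amygdala, accumbens and cingulate gyrus, and surrogate variables 3, 7, 2 and 21. A mean CPM of at least 1 gave 4, 0, 0 and 7. Males alone gave 0, 0, 0 and 5, females alone 0 in each region, and voom with the file number as a block 0 in each. RLE size factors gave 0 in the accumbens, and 2 genes passed there without the incomplete libraries. The cause was not tested, and no refit with lane was run for the letters.

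The 3 correlations of sex differences past the adjusted threshold lost it under 2 alternatives. At a mean CPM of at least 10 they were 0.315 for dentate gyrus and amygdala, 0.337 for dentate gyrus and accumbens and 0.296 for amygdala and accumbens (adjusted permutation p = 0.1, 0.059 and 0.06). Without the incomplete female library they were 0.303, 0.357 and 0.325 (adjusted permutation p = 0.059, 0.06 and 0.1); the first rests on the same libraries and moved through the adjustment alone. RLE size factors, which scale whole libraries, left adjusted permutation p at 0.03, 0.03 and 0.04. Lane in both fits moved r of the edgeR fold changes most where it could be fitted, without a test. The values went from 0.29 to 0.045 for dentate gyrus and amygdala and from 0.262 to -0.001 for dentate and cingulate gyri. For amygdala and cingulate gyrus they went from 0.313 to 0.222. Lane also raised the standard errors, which alone can lower r. The planned tests of the fixed symbol lists were not run, since the identifiers carry no symbols. These include the tests with preset or estimated correlation, with fry and with the file number as a block. What depth limits was not tested apart: at the real depths, dispersions and group sizes, 71.6% of genes with the smallest simulated change were called in the dentate gyrus comparison of the sexes.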

Other observations

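The sets of region-enriched genes were chosen after seeing the data, and so were the tests on them. In the sex comparison of the amygdala, 64 of 432 genes enriched in the cingulate gyrus were higher in females and 3 were higher in males, with a median log2 fold change of 0.06 (camera adjusted p = 0.00122 with a preset correlation of 0.01, adjusted p = 0.731 with an estimated correlation). In the accumbens, 166 of 485 genes enriched in the dentate gyrus were higher in females and 45 in males, with a median of 0.12 (camera adjusted p = 0.00126, adjusted p = 0.635 with an estimated correlation), and genes enriched in the cingulate gyrus were split 105 to 41 of 409 (camera adjusted p = 0.0344, adjusted p = 0.878 with an estimated correlation). In the cingulate gyrus, 27 of its 508 own enriched genes were higher in females and 1 in males (camera adjusted p = 0.0344, adjusted p = 0.635 with an estimated correlation). The other 12 of 16 tests did not pass, and with an estimated correlation none of the 16 passed.

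Over the 4 regions 223 genes were called higher in females in a region and higher in males in another. Opposite calls were 90 for the amygdala and the accumbens, 60 for the dentate gyrus and the accumbens, 22 for the dentate gyrus and the amygdala and 3 for the dentate and cingulate gyri. The accumbens and the cingulate gyrus shared 111 genes higher in females and 20 higher in males, where independent lists give 65.6 and 17.6, and 57 genes went opposite ways. The amygdala and the cingulate gyrus shared 101 and 16, where independent lists give 15.7 and 3, and 3 genes went opposite ways. The difference between these counts was not tested.

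3 libraries have a title that disagrees with a label and entered no comparison. BML3 and NML10 had 0 counts of ENSRNOG00000055225 and held ENSRNOG00000057231 at 118.7 and 136.1 CPM, within the range of males. Against the mean profiles of the regions, BML3, labelled dentate gyrus, correlated at -0.4 with that region, at 0.416 with the amygdala of its title and at 0.545 with the accumbens. NML10, labelled amygdala, correlated at 0.203 with that region and at 0.76 with the accumbens of its title. CFH5, whose label and title differ in sex only, correlated at 0.805 with the cingulate gyrus of both.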
